A study of Rattus norvegicus with 4 samples.

How the data were processed

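Total RNA of primary rat hippocampal neurons was sequenced before (input) and after (IP) immunoprecipitation with an m6A kit, and libraries were made with a directional kit, per the labels' protocols. The 4 samples formed 4 groups of 1 library each, taken from the sample titles: Ctrl_Input, Ctrl_IP, BPA_Input and BPA_IP. Neurons were grown with the mitotic inhibitor Ara-C from day 7 on, and exposure to BPA lasted 48 h at 1 mM, per the labels. The labels give day 12 to 14 in vitro for the BPA_IP sample and day 12 to 13 for the BPA_Input sample. They do not say whether input and IP came from 1 culture, and no culture was repeated.

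The submitters' processing notes name cutadapt 1.9.3, STAR and HISAT2 2.0.4, with no role or order. The quantifier, the peak caller's version and cut-off and the genome build are not given in the sources used here; contig names beginning with AABR06 occur among the gene names. Coordinates are therefore those of the files, and no genome was used. The starts in the files were taken as counted from 0, since the lengths given there equal end minus start, and are printed 1 higher, so that positions are 1-based. The deposited input tables give, per the file headers, an FPKM and a count for each gene. The deposited counts are estimated counts multiplied by 1 factor per library: low values were multiples of 1.01 in the Ctrl library and 1.02 in the BPA library, and 96.4% of values under 300 reads in both libraries came within 0.01 of a whole number after division by that step. DESeq2 size factors computed from the deposited counts were 1 in both libraries. The deposited peak lists name each peak as a MACS peak and give, per the file headers, a score equal to -10 × log10 of the p-value, a fold enrichment ratio of IP over input, an FDR in percent, which was 100 for each peak, and a peak length, which was end minus the start as deposited. Peaks were listed separately for each IP library, with the gene they fall in. Peak numbers ran to 13908 and 13193, above the 8192 and 8183 peaks listed, so the lists hold part of what was called. Scores and fold enrichments are the authors' values for each peak and were used to describe, rank or filter peaks within a list.

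From the deposited counts, log2((BPA + 1)/(Ctrl + 1)) was computed without further scaling for 13006 genes with a mean of at least 10 counts, and a log2 ratio of at least 1 in size counted as a difference. With 1 library per group no test between conditions was run and no p-value is given for a gene. Intervals of a ratio are exact (Clopper-Pearson) 95% binomial intervals from the reads rounded to whole numbers, and shares have Wilson 95% intervals. Both, and the floor of 3 reads used where a count was 0, cover counting error only, since reads were not tagged as molecules. The median of each gene list was placed among 10000 random lists of the same size drawn from 20 expression bins (2000 lists for gene classes of at least 2000 genes). Of 431 list genes, 421 matched the tables, 416 by symbol and 5 by gene number or Ensembl identifier through the GRCr8 RefSeq gene table, which was used for names only. Where a symbol had several rows, the row with most reads was taken. A second copy means another row with the same symbol, or with the same description once isoform notes and endings such as -like and its number are dropped, so members of 1 family can count as copies. Pathways were those of the deposited gene annotation.

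Peaks of both lists were compared by position, with at least 1 bp of overlap. Genes named in the text followed a rule set before the data were examined. It took the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 50 counts and a proper symbol. It took Mettl3, members of the m6A list at a log2 ratio of at least 0.58 in size, and up to 4 members of each other list with the largest ratio. It took the 5 strongest peaks of each list and the 5 strongest without an overlap, in genes with an FPKM of at least 1 in both inputs. For genes with peaks in both lists it took the 5 highest and 5 lowest ratios of the strongest peak's fold enrichment. A gene named by more than 1 part counts under each. Some genes that the rule takes are not reported here.

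The size rule and the list percentile were tested on simulated input libraries with 200 genes changed 3- or 6-fold. All changed genes were recovered with the right sign (100%), 48 unchanged genes of 13012 passed 2-fold from counting noise, none of them with a mean of at least 50, and a list of 20 genes raised by 0.15 on the log2 scale reached percentile 100. The simulated genes varied independently and by counting noise only, and the real libraries spread more widely. The shift of 0.15 was larger in size than the median of any of the 23 gene lists with all measured members in the main setting. No smaller shift and no list without a shift was run, so false calls of lists were not tested. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 50, centring on the median, DESeq2 size factors, stricter peak thresholds (fold enrichment of at least 5, score of at least 100), an overlap of 50% of both peaks, and genes with an FPKM of at least 1. Alternatives added after seeing the data were TMM factors, FPKM, leaving out genes with a second copy, matching random lists on length as well, and other score thresholds. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors only. Motif content and the place of peaks in UTRs or coding sequence were not analysed here, since they need a genome of the same build.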

Results

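The series compared rat hippocampal neurons in primary culture that were exposed to bisphenol A (BPA, a plasticiser with hormone-like activity) with untreated cultures. RNA was profiled by m6A immunoprecipitation sequencing, in which an antibody against the methylated base m6A (the most abundant internal modification of mRNA) pulls down RNA fragments and the same RNA before pull-down is sequenced as the input. There were 4 samples, 1 library in each of the groups Ctrl_Input, Ctrl_IP, BPA_Input and BPA_IP. Per the labels, the dose was 1 mM for 48 h, begun on day 12 in vitro; the end is given as day 14 for the immunoprecipitated sample and as day 13 for the input. The input tables listed 22714 genes, with deposited counts summing to 9837064 in the Ctrl library and 9774929 in the BPA library. The peak lists held 8192 and 8183 m6A peaks. No group had a replicate, so every difference below is between 2 libraries, carries no test of the exposure, and has an error that covers read counting only.

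The first comparison asked which transcripts differed in level between exposed and untreated neurons. A small set of genes stood far apart between the inputs while most of the transcriptome did not move: 263 of 13006 genes with a mean of at least 10 counts (2.02%) differed by 2-fold or more, 135 of them higher and 128 lower in the BPA library. Among genes with a proper symbol and a mean of at least 50 counts, the lowest were Ppp1r3c, RragB and Ncbp2. Ppp1r3c, a subunit that directs a phosphatase to glycogen, had 261 counts in the Ctrl library and 0 in the BPA library. It was at least 85.3-fold lower, against a floor of 3 reads. Summed with its second row it had 306 and 27.6 counts, a log2 ratio of -3.42. RragB is a small GTPase of amino acid signalling to mTOR, and Ncbp2 a subunit of the nuclear cap-binding complex. Hspa1a, the stress-inducible heat shock protein, fell from 104 to 10.2 counts, 10.2-fold lower (95% interval 5.31 to 21.8). Another listed gene, Hspa1b, bears a related symbol but does not count as a second copy by the name rule. Whether reads moved between Hspa1a and Hspa1b was not tested. By the same rule the highest were Dpysl5, Brms1 and Cttn. Dpysl5, a protein of axon guidance, had 4.04 counts in the Ctrl library and 218 in the BPA library, and Brms1 had 3.03 and 145. Cttn (cortactin, which binds branched actin filaments) had 45.4 and 427 counts, 9.41-fold higher (interval 6.91 to 13.1).

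This ranking took the genes with a proper symbol among the 10945 genes with a mean of at least 50 counts. Of all 10945, 26 were higher and 26 lower by 2-fold or more. Rows named only by an identifier were left out of the ranking, such as MGC94199 (log2 ratio -5.57) and MGC109340 (4.49). RragB went from 106 to 1.02 counts (log2 ratio -5.73) and Ncbp2 from 149 to 11.2 (-3.62). The remaining low genes were Fam131a (-3.01), the ribosomal protein gene Rpl8 (-2.82), the aminopeptidase Lnpep (-2.37), the kinase Pak2 (-2.14), Ppfia4 (-1.71), Rps27a on chromosome 14 (-1.66), the kinase Map3k7 (-1.61) and Ncan, the brain matrix proteoglycan neurocan (-1.57, 675 and 227 counts). The remaining high genes were the translation termination factor Gspt1 (2.55), Hmgb3 (2.50), the RNA-binding Ewsr1 (2.48), the neuronal enolase Eno2 (1.78, 37.4 and 131 counts), Gstm5 (1.61), a second Rps27a row on chromosome 5 (1.52), the mitochondrial protease Yme1l1 (1.26), Atg4b of autophagy (1.13) and the tubulin deacetylase Hdac6 (1.12). The Eno2 row was low, with an FPKM of 1.68 in the Ctrl library and 5.88 in the BPA library. It has no second copy by the name rule, and whether reads moved between it and related rows was not tested. In the coordinates of the files, Ppp1r3c lies on chromosome 1 from 262671064 to 262674270, Dpysl5 on chromosome 6 from 36210780 to 36304252 and Cttn on chromosome 1 from 224459486 to 224494902. Of the 52 genes, 25 (48.1%, Wilson 95% interval 35.1 to 61.3) had another row of the same name or description in the table, against 8.31% of the other genes at this depth; Ppp1r3c, RragB, Ncbp2, Fam131a, Rpl8, Lnpep, Pak2, Map3k7, Cttn, Hmgb3 and Gstm5 were among them, and Dpysl5 and Brms1 by the description of a related family member. The Rps27a rows moved in opposite directions, and their sum went from 1674 to 1478 counts, whereas the other rows of Ncbp2, Fam131a, Cttn and Gstm5 had 0 counts in both libraries. Summed with their other rows, the log2 ratios were smaller for RragB (-3.70), Rpl8 (-1.69), Lnpep (-1.21) and Map3k7 (-1.14), and those of Dpysl5 (0.05) and Brms1 (0.43) were set mostly by the other family members. On the FPKM + 1 scale, Ppfia4 (-0.96), Map3k7 (-0.87), Atg4b (0.92) and Hdac6 (0.71) no longer reached 2-fold.

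**Figure D1:**
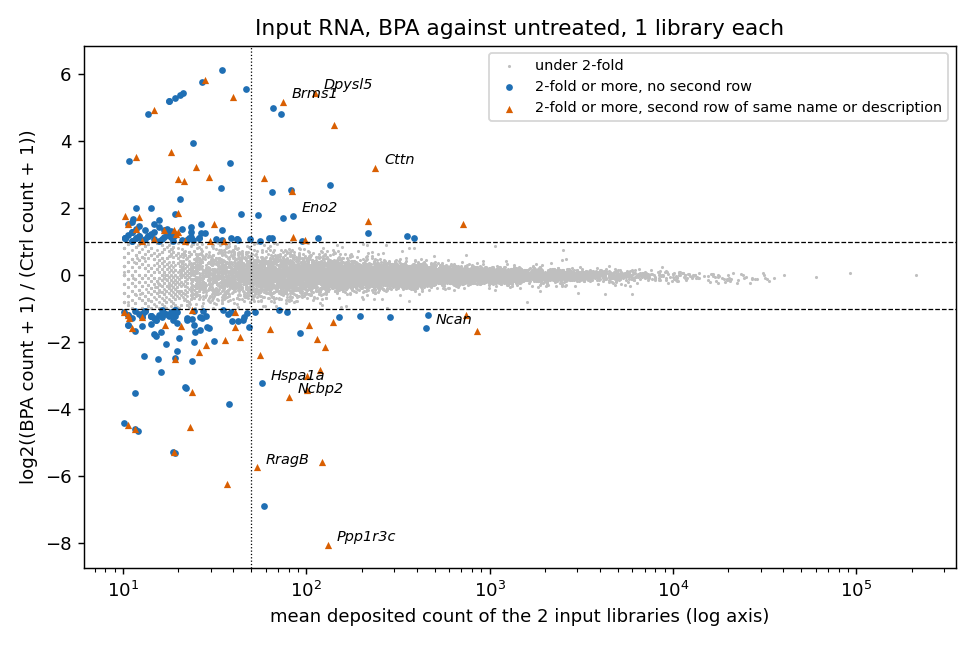
Each point is 1 gene with a mean of at least 10 counts; the horizontal axis is the mean deposited count of the input libraries (log axis) and the vertical axis the log2 ratio of BPA to Ctrl counts after adding 1, with dashed lines at 2-fold and a dotted line at a mean of 50. The 263 genes past 2-fold lie mostly at low counts, and orange triangles mark those with a second row of the same name or description.

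Precision followed depth. Between 10 and 30 counts, 179 of 1275 genes passed 2-fold, between 300 and 1000 counts 7 of 3884, and none of the 1798 genes from 1000 to 3000 or the 533 above 3000. The central 68% of log2 ratios spanned 0.626 either side at 10 to 30 counts and 0.0859 above 3000, where counting alone gives 0.493 and 0.0284. Across genes, which are not independent replicates, the libraries correlated with Pearson's r of 0.981 and Spearman's rho of 0.993.

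Gene lists written down before the data were examined showed coordinated but small differences. Of 23 lists, 6 had a median log2 ratio outside the central 95% of 10000 random lists matched on expression, where chance gives 1.15 if list members vary independently. Members of a random list were drawn singly, so these lists do not carry a tendency of related genes to vary together between cultures. Cholesterol and isoprenoid synthesis was highest, with a median of 0.14 (10.6% higher, percentile 100) and 18 of 20 members higher in the BPA library. Its largest ratios belonged to the lanosterol demethylase Cyp51 (1.21-fold, 95% interval 1.16 to 1.26), the sterol dehydrogenase Nsdhl (1.20-fold, 1.05 to 1.38), the sterol sensor Insig1 (1.18-fold, 1.09 to 1.27) and Stard4 (1.16-fold, 0.982 to 1.37). Synaptic lists rose on both sides of the synapse. Ionotropic glutamate receptors and the postsynaptic scaffold had a median of 0.10 (percentile 100, 19 of 23 higher), with the kinase CAMK2A at 1.17-fold, the receptor subunit Grin2a at 1.15-fold and the scaffold Shank3 at 1.13-fold, while Grin3a went the other way (0.628-fold, 0.431 to 0.908). Presynaptic vesicle machinery had a median of 0.08 (percentile 99.9, 15 of 20 higher), led by Cplx1 (1.20-fold, 1.10 to 1.30), Stx1a (1.18-fold), the vesicular glutamate transporter Slc17a7 (1.18-fold) and the active zone protein Bsn (1.15-fold).

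In the opposite direction, transcripts of the mitochondrial genome had a median of -0.15 (-9.67%, percentile 0), with 9 of 11 lower, among them Mt-nd4l (0.780-fold, 0.729 to 0.833), Mt-nd2, Mt-atp8 and Mt-nd4 (each 0.855- to 0.859-fold). The nuclear-encoded respiratory chain did not follow (median 0.05, percentile 96.7; Cox4i1 1.09-fold). NRF2 oxidative stress targets had a median of -0.10 (percentile 0.080, 16 of 18 lower); the metallothioneins Mt2A (0.799-fold) and Mt1 (0.816-fold) and the glutathione transferase Gsta1 (0.804-fold) had the largest decreases, and Osgin1 was at 1.18-fold. Without genes that have a second row of the same name or description, the NRF2 list moved to -0.06 (percentile 3.62, 15 members) and left the outer range. Astrocyte markers had a median of -0.08 (percentile 1.35, 13 of 15 lower), with Sox9 at 0.884-fold, S100b at 0.886-fold, Ntsr2 at 0.888-fold and the gap junction protein Gja1 at 0.890-fold; this fall stood beside the rise of the synaptic lists in the same pair of libraries. No member of these 6 lists passed 2-fold.

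As a list, the m6A machinery did not stand apart. Mettl3, the catalytic subunit of the methyltransferase, had 286 counts in the Ctrl library and 292 in the BPA library (1.02-fold, 95% interval 0.865 to 1.21). The 18 measured writers, erasers and readers had a median of 0.0033 (percentile 50.02, 10 higher and 8 lower). The reader helicase Ythdc2 was the only member past the 0.58 log2 mark, at 186 and 117 counts (0.627-fold, 0.492 to 0.797). Some members under that mark also had counting intervals that left out 1. Cbll1 (0.791-fold, 0.709 to 0.883) and Fmr1 (0.835-fold, 0.758 to 0.918) were lower, and Rbm15 (1.16-fold, 1.02 to 1.31) was higher.

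Other neuronal and stress lists lay inside the range of random lists. Immediate-early and activity-regulated genes had a median of -0.05 (percentile 15.4), although Fos (0.633-fold, 0.514 to 0.779), Dusp1 (0.582-fold), Ier2 (0.633-fold) and Fosb (16.2 and 5.11 counts) were all lower. GABAergic genes were at -0.05 (percentile 9.30), with Pvalb at 36.3 and 12.3 counts, Sst at 0.767-fold and Slc32a1 at 1.17-fold. Dendrite, axon and cytoskeleton genes were at 0.04 (percentile 95.6; Dcx 1.16-fold, Nefl 1.13-fold). The integrated stress and unfolded protein responses were at 0.02 (percentile 73.1; Trib3 1.65-fold, Ddit4 1.22-fold, Atf3 0.765-fold), heat shock proteins at -0.07 (percentile 6.03; Hspa1a above, Dnajb1 1.12-fold), and p53 targets at -0.003 (percentile 43.3; Bbc3 1.27-fold, Bak1 0.835-fold). Xenobiotic and steroid receptors and their targets, which include the oestrogen receptors, were at -0.06 (percentile 10.4, 6 members higher and 13 lower). Against that balance, Ahr, the dioxin receptor, had 26.4 and 56.9 counts (2.16-fold, 1.35 to 3.62). Esrrg was at 1.88-fold and Cyp1b1 at 1.46-fold. Glycolysis and hypoxia genes were at 0.02 (percentile 75.8, Tpi1 0.525-fold, Eno2 3.50-fold) and fatty acid genes at 0.07 (percentile 96.3, Srebf1 1.16-fold, Fasn 1.11-fold). Ribosomal proteins were at -0.001 (percentile 50.5, Rpl13 1.13-fold). Of these, 2 were lower by 2-fold or more, Rpl8 and the chromosome 14 row of Rps27a, both given above.

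Lists for other cell types were likewise inside it, apart from the astrocyte list above. Microglia markers had a median of -0.10 (percentile 6.73; Cd68 0.766-fold, Tmem119 1.68-fold); with members of at least 50 counts alone the median was -0.16 (9 members, percentile 0.970). Oligodendrocyte markers were at 0.09 (percentile 91.7; Mag 13.1 and 28.6 counts), vascular and fibroblast markers at 0.08 (percentile 91.7; Col1a2 2.15-fold, 1.84 to 2.52, and Tagln 0.690-fold), inflammation genes at -0.07 (percentile 10.4; C3 0.719-fold, 0.674 to 0.768, and Ccl2 0.589-fold) and cell cycle genes at -0.09 (percentile 11.9; Cdc20 0.527-fold, Cenpf 0.662-fold).

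**Figure D2:**
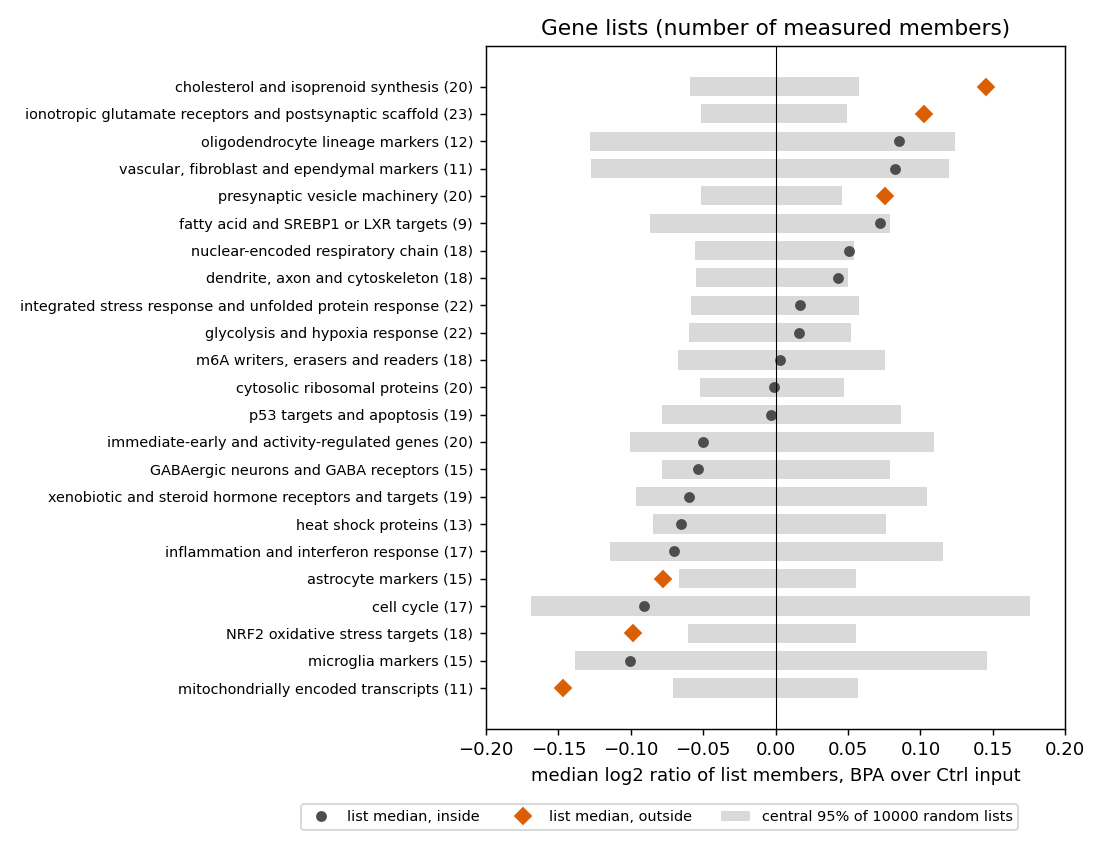
Median log2 ratio of each list's measured members (horizontal axis, BPA over Ctrl input), with the number of members in brackets; grey bars span the central 95% of 10000 random lists matched on expression. Orange diamonds mark the 6 medians outside it, 3 above and 3 below.

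The second comparison asked whether m6A sites differed after exposure. The lists were alike in size and in median peak length: 8192 peaks in 4050 genes in the Ctrl list and 8183 peaks in 4088 genes in the BPA list, with median lengths of 159 and 160 bp. The authors' fold enrichment of IP over input had medians of 5.92 (interquartile range 4.43 to 8.41) and 6.28 (4.70 to 9.05). By position, 6005 of the Ctrl peaks (73.3%, Wilson 95% interval 72.3 to 74.3) overlapped a BPA peak by at least 1 bp, and 6006 of the BPA peaks (73.4%, 72.4 to 74.3) overlapped a Ctrl peak. Of these, 5708 had the same start and end in both lists (95.1% of the Ctrl peaks with an overlap). Whether these edges were set by the peak caller or by annotated units was not tested, and this bears on what alike lengths and overlaps show. The lowest score in both lists was 3.02, which by its header is a p of 0.499, and 30.6% of Ctrl and 28.7% of BPA peaks had a p above 0.05.

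Overlap rose steeply with the peak's score within its own list. Of Ctrl peaks with a score under 10, 44.7% (42.6 to 46.9) overlapped a BPA peak, against 96.6% (94.6 to 97.9) of those with a score of 1000 or more; the BPA list gave 44.3% (42.0 to 46.5) and 96.0% (94.0 to 97.3). Peaks without an overlap had median scores of 9.47 in the Ctrl list and 10.4 in the BPA list, and overlapping peaks had 66.5 and 69.4. Among peaks with a score of at least 100, 94.5% of 2595 Ctrl peaks and 93.6% of 2724 BPA peaks overlapped the full other list.

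**Figure D3:**
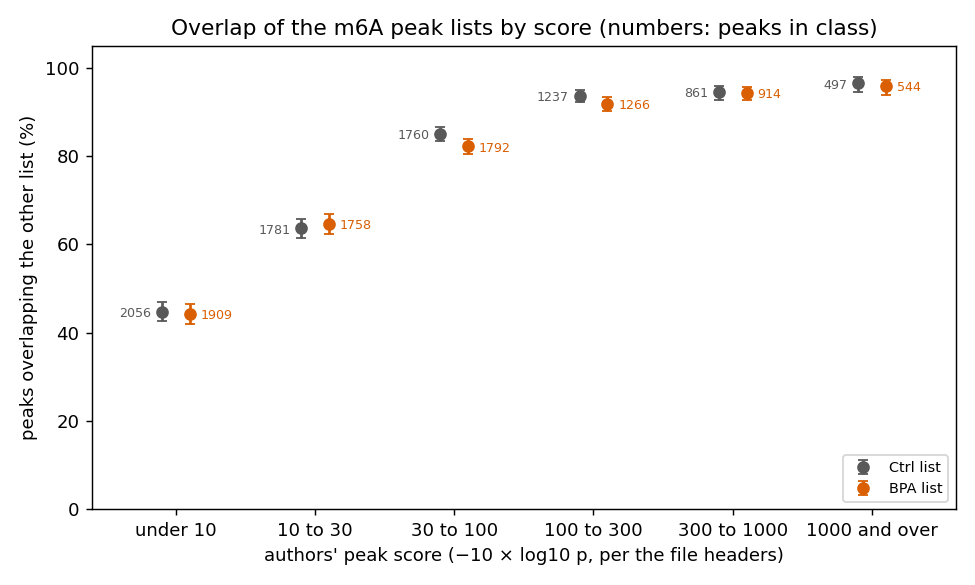
Percent of peaks in each score class (horizontal axis, the authors' score) that overlap the other list by at least 1 bp (vertical axis), for the Ctrl list in grey and the BPA list in orange; bars are Wilson 95% intervals and the numbers give the peaks in each class. Overlap climbs from 44.7% and 44.3% in the lowest class to 96.6% and 96.0% in the highest.

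The strongest peaks were largely common to both lists. In the files' coordinates, the peak at chromosome 6, 39264759 to 39265169, in AABR06042582.1 was the strongest of both lists among genes with an FPKM of at least 1 in both inputs, with fold enrichments of 488 (Ctrl) and 450 (BPA). A 468 bp peak in LOC257642, described as an rRNA promoter binding protein (chromosome 14, 46699273 to 46699740), had 109 and 103, a peak in AABR06027146.1 (chromosome 3, 156559482 to 156559662) had 99.1 and 116, and one in Bccip (chromosome 1, 212726542 to 212726728) had 88.6 and 117. A peak in Ehbp1l1 (chromosome 1, 228000007 to 228000130) had a fold enrichment of 307 in the Ctrl list and 13.4 in the BPA list. In Pcca, a subunit of propionyl-CoA carboxylase, the Ctrl peak (chromosome 15, 112367373 to 112367440, fold enrichment 187) and the BPA peak (112367257 to 112367277, also 187) did not overlap and lay 95 bp apart.

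Besides Pcca, the strongest Ctrl peaks without an overlap lay in Ap3d1 (fold enrichment 31.1; chromosome 7, 12034195 to 12034360), the cohesin gene Smc1a (27.9; X, 21726645 to 21726883), Cdk11b (24.1; 5, 176542671 to 176542845) and Ddrgk1 (23.5; 3, 129703262 to 129703468). Strong BPA peaks without an overlap lay in the mRNA export gene Thoc2 (29.6; X, 128264409 to 128264839), Dek (29.5; 17, 19969856 to 19970015) and LOC100361103 (26.6; 4, 242815814 to 242816296). Apart from LOC100361103, these genes had between 2 and 8 peaks in the opposite list, and the nearest opposite peak of Ap3d1, Smc1a, Cdk11b and Ddrgk1 was 661 to 977 bp away, that of Dek 5444 bp, that of Thoc2 6583 bp and that of LOC100361103 544255 bp.

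At gene level, 3357 genes had a peak in both lists, 693 in the Ctrl list only and 731 in the BPA list only. With a score of at least 100 in the list asked about, the genes in 1 list only were 38 and 49. For the 3113 genes with a peak in both lists and an FPKM of at least 1 in both inputs, the strongest peak's fold enrichment lay within 2-fold between the lists in 98.4%; the strongest peak need not be at the same position. The genes furthest apart with the higher value in the Ctrl list were Ehbp1l1 (307 and 13.4), Oraov1 (46.4 and 5.92), Bag1 (7.43 and 2.55), Arhgap12 (9.98 and 3.99) and Rpl39 (14.3 and 5.74). Those with the higher value in the BPA list were Sap30l (2.42 in the Ctrl list and 13.5 in the BPA list), LOC100362333 (6.47 and 32.6), the metallothionein Mt1m (14.0 and 56.8), Agbl5 (3.69 and 11.8) and Thoc2 (9.35 and 29.6). Mt1m rested on 2.02 and 2.04 input counts. In the list with the lower value, the gene's highest score was under 10 for Sap30l (5.42), Agbl5 (3.99), Bag1 (4.02) and Rpl39 (6.58). The other genes named here had higher scores in both lists. Enrichment values come from 1 library per list, so these pairs describe the lists and have no replicate error.

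The last comparison set a gene's place in the peak lists beside its input ratio. Genes with a peak in the BPA list only had a slightly lower input ratio (median log2 -0.03, 671 genes, percentile 0 among random lists matched on expression), and genes with a peak in the Ctrl list only a slightly higher one (0.02, 621 genes, percentile 99.7). Genes with peaks in both were at -0.006 (3129 genes, percentile 0.925) and genes in neither at 0.007 (8501 genes, percentile 98.4). Of the BPA-only genes 9 were higher and 7 lower by 2-fold or more, and of the Ctrl-only genes 7 were higher and 8 lower. With a score of at least 100 for having a peak, the 36 BPA-only genes were at -0.04 (percentile 6.68) and the 30 Ctrl-only genes at 0.05 (percentile 92.0), inside the range of random lists. Peaks were called as enrichment over the same inputs, so an error that lowers a gene's BPA input favours a BPA-only call, and the random lists do not carry this link; the class medians describe the lists and do not separate it from a difference in expression.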

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

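The FPKM, second-copy, TMM, length-matched, p of 0.05, score of 50 and score of 100 in both lists settings were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and the alternatives that need replicates (DESeq2's test, leaving out a replicate, a replicate block) were not run; nor were those on motifs. The number of genes past 2-fold depended on the treatment of low counts: 263 became 170 (81 higher) with a pseudocount of 5, 1946 (1028 higher, 918 lower) with no filter and 52 (26 higher, 26 lower) with a mean of at least 50 counts, the last because fewer genes were tested; with FPKM 84 were higher. All 170 genes under a pseudocount of 5 were among the 263, and 99 of the 180 under FPKM were. Centring, DESeq2 factors and TMM factors left 263, the DESeq2 factors being 1 in both libraries. Of 944 values for 110 named genes 13 moved beyond their counting interval, 12 of them under FPKM, and 0 changed sign. Of 161 list medians 3 moved by more than the spread of random lists. They were the NRF2 and ribosomal lists without genes with a second copy, and the oligodendrocyte list under FPKM (0.02, 8 members, percentile 65.2). None of the 6 lists outside the central 95% changed sign. There were 2 medians near 0 that did, that of p53 targets (-0.003, and 0.03 with a mean of at least 50) and that of ribosomal proteins (-0.001, and 0.11 without genes with a second copy). The number of lists outside the central 95% was 6 or 7 in each setting. The mean of at least 50 added the microglia list, and leaving out genes with a second copy removed the NRF2 list and added ribosomal proteins (5 members, percentile 99.0).

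Peak numbers fell by construction with stricter thresholds: to 5340 (Ctrl) with a fold enrichment of at least 5, to 3588 and 3743 with a score of at least 50, and to 2595 and 2724 with a score of at least 100. Shared percentages went from 73.3 and 73.4 to 85.9 and 83.4 with a fold enrichment of at least 5, and to 94.5 and 93.6 with a score of at least 100, against all peaks of the other list; with a score of at least 100 in both lists they were 78.3 and 74.6. Genes with peaks in 1 list only fell from 693 and 731 to 243 and 344 (fold enrichment) and to 38 and 49 (score). With the score threshold the class medians were -0.010 for genes in both lists, 0.045 for Ctrl only and -0.039 for BPA only; they kept their direction, and the cause of the movement was not tested.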

Other observations

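The tests on second copies, on astrocytes and neurons and on distances of 1000 bp were chosen after the result was seen, as was the weighing of the shared input. Gene groups differed in how many of their genes carried an m6A peak in both lists. A difference between the lists was not tested. The random genes here were matched on expression and not on transcript length, so a part played by length in these shares was not tested. The breakdown by gene group and the genes named in this part were chosen after the values were seen, except list members fixed beforehand. Of 18 measured dendrite, axon and cytoskeleton genes, 11 had a peak in both lists (61.1%), against 34.0% in random genes of matched expression (percentile 99.0); the growth cone protein gene Gap43 had a fold enrichment of 52.4 in the Ctrl list and 62.8 in the BPA list, and the neurofilament gene Nefm 27.6 and 28.5. Of 20 presynaptic genes, 12 had one in both (60.0%, random 34.8%, percentile 98.8). Of 18 measured m6A machinery genes, 7 had peaks in both lists (38.9%, percentile 77.6); the writer complex gene Zc3h13 had 10 peaks in each list with a strongest fold enrichment of 46.1 and 49.8. None of 18 nuclear-encoded respiratory chain genes (random 35.2%), 20 ribosomal protein genes (random 34.7%) or 11 mitochondrial transcripts (random 34.5%) had a peak in both lists, and 2 of 22 glycolysis genes did (percentile 1.16). Of these 20 ribosomal protein genes, 1 had a peak in the Ctrl list only and 3 in the BPA list only. The wider annotated pathways were low but not empty. Peaks in both lists were found in 15 of 95 oxidative phosphorylation genes (15.8%, random 31.6%) and 23 of 130 ribosome genes (17.7%, random 27.9%). Among pathways in the deposited annotation, 66 of 119 spliceosome genes (55.5%, random 27.0%) and 113 of 895 metabolic pathway genes (12.6%, random 25.8%) had peaks in both. With each gene's locus, introns included, divided into 10 equal parts, 21.2% of Ctrl and 21.6% of BPA peaks lay in the first part and 12.1% and 12.3% in the last.

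The complement and coagulation pathway, singled out after the values of 254 pathways were seen, had a median log2 ratio of -0.20 over 34 genes, 25 of them lower and 9 higher in the BPA input, at percentile 0 among random lists matched on expression and length. Of the 254 pathways 6 lay below percentile 0.1, where chance gives 0.254 if genes vary independently. Some of the 6 share genes and are not separate results. C3 and C3ar1 were leading genes of both this pathway and Staphylococcus aureus infection, and RT1-CE7 of both cell adhesion molecules and antigen processing. C3, a member of the complement pathway, had 2193 counts in the Ctrl library and 1577 in the BPA library. In the same library the astrocyte list had a median of -0.08 (percentile 1.35) and the microglia list -0.10 (percentile 6.73). The 9 microglia members of at least 50 counts were at -0.16 (percentile 0.970). The oligodendrocyte list was at 0.09 (percentile 91.7), and at 0.02 under FPKM (8 members, percentile 65.2). The synaptic vesicle cycle pathway was at 0.07 over 52 genes, 32 of them higher, at percentile 100. Its leading gene Cplx1 is also in the presynaptic list, so the pathway is not a separate result. Pathways close to other shifted lists lay inside the central 95%. Steroid biosynthesis was at 0.07 (15 genes, percentile 94.5) and glutamatergic synapse at 0.02 (93 genes, percentile 96.6). Astrocyte transcripts were abundant in both inputs despite the label of primary neurons: Gfap had 61142 counts in the Ctrl library and 58954 in the BPA library.

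The first pattern is the set of 52 well-covered genes that differed by 2-fold or more between the inputs. Counting noise alone is argued against, since 88.5% of them (46 of 52, Wilson 95% interval 77.0 to 94.6) passed an exact binomial test of their reads at 0.05 divided by 10945 genes, which compares these libraries and not the conditions. Of the set 48.1% had a second row of the same name or description, against 9.08% on average in random genes of matched expression. Reads moving between the listed rows are argued against for most of the 21 genes where counting error allowed the test. In 9.52% (2 of 21, 2.65 to 28.9) the copies moved the opposite way by at least 50% of the gene's change. Both were Rps27a rows, each the other's copy, which the interval counts as separate. The copies of Ncbp2, MGC94199, Fam131a, Cttn and Gstm5 had 0 counts in both libraries, so no offset could be seen there. The name rule misses some relatives, and with rows of the same symbol stem counted 9.62% (5 of 52, 4.18 to 20.6) had none, Ewsr1 and Ncan among them, which does not decide whether copies of some kind bear on the whole set. Copies outside the table, and reads dropped or given to rows of other names, were not tested. An effect of BPA stays open and untested.

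The second pattern is the small rise of synaptic and cholesterol genes beside the small fall of mitochondrial and astrocyte transcripts. A trend with transcript length is argued against for the postsynaptic list, which stayed at percentile 99.98 when random lists were matched on length as well as expression. A larger share of neurons in the BPA culture could raise neuronal genes at large, and of the 33 members of the other neuronal lists, GABAergic and dendrite or axon, 18 were higher (54.5%, Wilson 95% interval 38.0 to 70.2). Within these, 10 of 15 GABAergic genes were lower, and so were Map2 (0.974-fold) and Mapt (0.931-fold), while 13 of 18 dendrite and axon genes were higher, with both medians inside the range of random lists. The interval leaves that explanation undecided, and with 1 library per condition a difference in cell make-up and an effect of BPA cannot be told apart.

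The third pattern is the peaks found in 1 list only, which had mostly low scores: of peaks with a score under 100, 36.5% of the Ctrl and 36.7% of the BPA peaks lacked an overlap, against 5.47% and 6.42% of stronger peaks, and why was not tested. The median input log2 ratio of BPA-only genes differed from that of Ctrl-only genes by -0.051, beyond the random splits (-0.025 to 0.024). This does not decide whether input expression set the calls. The input is also the denominator of the calls, which was left out of the prediction made in advance. Counting error in 1 such gene's log2 ratio, about 0.112, enters both its ratio and its call. That value is not the error of the difference between medians. For the 317 unshared peaks with a score of at least 100, a split or shifted call and a true difference cannot be told apart: 2.21% had a peak of the other list within 500 bp, but 29 of 16333 neighbouring peaks within a list lay that close, so the distance set in advance could hardly be met. Within 1000 bp, 28.4% had a non-overlapping peak of the other list against 8.72% of the overlapping peaks. Of the 317, 71.3% (66.1 to 76.0) lay in a gene with another peak in the other list, and an effect of BPA on them stays open.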
